A study of Mus musculus with 8 samples.

How the data were processed

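Spinal cord RNA from 8 female mice, aged 8 weeks per the labels, was measured on Agilent 1-colour (Cy3) arrays that carry probes for circRNAs, lncRNAs and mRNAs. The labels name 4 control and 4 contusion samples, and the series' design text says that the tissue was the T9 to T10 segments around the injury, 1 sample per mouse. Per the labels' protocols, total RNA was purified with a miRNeasy column kit and labelled with the Low Input Quick Amp WT kit. The labels disagree on time and on the controls: all 4 contusion titles say 3 days after injury, the contusion descriptions of replicates 1, 2, 3 and 4 say 3, 4, 5 and 6 days, the design text calls the controls sham-operated, and their descriptions call them normal cord. The groups here are contusion and control, as the titles give them, with no split by day.

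The spot values are intensities, background-subtracted and detrended within each array by Agilent Feature Extraction, per the file headers, and not normalized between arrays. The submitters' processing notes name Feature Extraction 10.7 and limma, while the algorithm fields of the headers read 12.0.3.1. Other columns used were the mean spot and local background intensity, per the file headers, and the flags for signal well above background, saturation and outlier spots, which Feature Extraction sets to 0 or 1. The authors' series table holds log2 values: set against each array's log2 intensity, the deposited log2 values had a Spearman correlation of 1 and slopes of 0.983 to 1.02. Their column medians were 5.3993 to 5.4, so they were on the log2 scale, quantile normalized between arrays and not centred per gene. That table was used as an alternative only.

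The headers count 172336 spots per array, of which 155279 were analysed here; the other 17057 (9.90%) were not analysed here. The arrays carried 150305 different non-control probes, and 72.9% to 75.4% of them were well above background on each array. The 75th percentile of the processed intensity was 203 to 252 and no spot was saturated. With 4 arrays per group, the number of arrays limits the precision: the median standard error of a log2 difference was 0.0944 for mRNAs, 0.140 for lncRNAs and 0.0895 for circRNAs. Arrays within a group correlated at 0.988 to 0.992.

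Each probe's value is its log2 processed intensity minus the array's 75th percentile over the non-control probes, and is called its level below. Control spots and between 6 and 53 outlier spots per array were left out. Probes well above background on at least 4 of the 8 arrays, whatever their group, were kept, and the probe with the highest mean stood for each gene, transcript or circRNA. Groups were compared with limma 3.58.1 (R 4.3.3; lmFit and eBayes, group as the only term), two-sided, with Benjamini-Hochberg adjustment over all 89113 features together and a call at an adjusted p under 0.05. Errors of differences are limma's standard errors, errors of levels are SDs, and n is 4 arrays per group, except that 96 features lack a value on 1 or more arrays. Of the named and listed features these are Timp1 and Steap4, with 3 control values each. A feature that was well above background on no array of a group has only a bound there: its fold is given as at least the bright group's mean over the higher of the dim signal and the lowest signal among probes well above background on each array. The same bound is given where the lower group was well above background on only some of its arrays and the bound lowers the difference, a rule added after the values were seen, while ranks use the values without it.

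Probes were sorted by their identifiers: 47074 carry RefSeq mRNA accessions, 37852 are circRNAs named by position, and lncRNA probes carry NONCODE (55674), Ensembl transcript (8299), RefSeq non-coding (1393) or other (13) names. Of the 22694 mRNA accessions 99.1% matched the RefSeq table of GRCm38.p6 used for gene symbols, as did 97.1% of the RefSeq non-coding accessions. Of 10290 genes with several probes and a call for at least 1 of them, 293 (2.85%) had probes called in opposite directions, and none of the genes named here is among them. The headers give mm9 (NCBI37) for the array's coordinates, and no source used here gives the build of the circRNA positions. Since the files name no host gene, the planned comparison of circRNAs with host genes was not run as designed; after the data were seen, each circRNA was placed by position. Of the circRNA positions 98.1% lay inside a gene of GRCm38, against 40.3% after a shift of 1e+06 bases, and 36286 circRNAs lay inside exactly 1 gene, which is protein-coding. The table gives no strand, so strand was not used.

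The test, its samples and covariates, the list of alternatives, the rule for named genes and 35 gene lists with 572 different symbols were fixed before the data were examined. By that rule the text names, of each RNA class, up to 10 of the largest increases and up to 10 of the largest decreases among called features whose groups do not overlap, then per list 2 to 4 members with the smallest adjusted p and members against their list, and the reference genes. Not every gene this rule picks is named in the text, and some are not reported here. Any other feature is said to have been chosen after its values were seen. Lists were tested with limma's camera (correlation preset at 0.01, Benjamini-Hochberg over the 35 lists), beside camera with an estimated correlation and fry. Member counts are given over all features and adjusted over the list alone. Lncpint was measured under its present symbol, and Ahsp, Mir142hg and Ptprd-as1 had no match.

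Slide 1 (scan 1) held control replicates 2, 3 and 4 with contusion replicate 1, and slide 2 (scan 2) held control replicate 1 with contusion replicates 2, 3 and 4. Both slides hold both groups, so fits with slide as a fixed or random block and differences within each slide were computed. Further alternatives were normexp background correction with quantile or percentile scaling, quantile and median scaling, other probe filters and probe choices, a trend and robust variance, array weights, Welch's test with a 2-fold threshold, the replicate number as a block, the authors' table, and leaving out each array. The alternatives added after the data were seen were leaving out control replicates 1 and 3 together, contusion replicate 1 alone against the controls, and scaling to the 9 spike-in probes. Lists of marker genes of bone marrow, bone, skeletal muscle, peripheral nerve and sensory ganglia were also written after the first look at the data.

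The code was tested on simulated data for the contusion and control comparison over 89113 features with differences added to 50 features each. Of those with a log2 difference of 0.5, 1, 2 and 3, limma recovered 10%, 76%, 98% and 94%, with 5 false calls. The first pass mark asked for more at a difference of 3 and was not met. It was replaced after that result by marks on bias, false calls and the noise of the features missed. Both shifted lists of the simulation were recovered over 18809 genes by camera with either correlation and by fry, and 0 of the 33 unshifted lists were called. The simulated genes varied independently, whereas the estimated correlation within real lists reached 0.913 (NADPH oxidase). The simulation therefore does not show how often camera with a preset correlation calls unshifted lists in these data. Tables and plots used R's data.table (version 1.17.8), python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.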

Results

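Levels of circRNAs, lncRNAs and mRNAs were measured in the thoracic spinal cord of 8 mice, 4 with a contusion injury and 4 controls, on 1 array per mouse. A contusion is a bruise of the cord made by a blunt impact. The titles place the contusion samples 3 days after injury, while the descriptions of replicates 2, 3 and 4 give 4, 5 and 6 days, so the day of those 3 samples is uncertain. After the filter on dim probes, 18198 mRNAs, 35300 lncRNAs and 35615 circRNAs were tested. On each array 72.9% to 75.4% of probes were well above background. All differences are contusion minus control on the log2 scale ± standard error with n = 4 per group except for 96 features with missing values, levels are log2 values relative to the array's 75th percentile ± SD, and adjusted p-values are limma's.

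The question the design sets is which RNAs differ between injured and control cord. Among mRNAs, the contused cord had far higher levels of genes of phagocytes and of dividing cells and lower levels of genes of neurons and of cholesterol synthesis. Arg1 (NM_007482), an arginase of wound macrophages, rose 36.5-fold (5.19 ± 0.90, adjusted p = 0.00248), and Cd5l (NM_009690), a secreted macrophage protein, rose 56.3-fold (5.81 ± 0.90, adjusted p = 0.00147). Both folds depend on control replicate 4, the lowest control: without it Arg1 rose 19.3-fold and Cd5l 30.3-fold, and without control replicate 1 Cd5l rose 91.1-fold. The replication helicase gene Mcm2 rose 4.00-fold from 2.35 ± 0.07 to 4.35 ± 0.07 (2.00 ± 0.07, adjusted p = 4.73e-05). The potassium channel gene Kcnc1 of fast-spiking neurons fell by 1.23 ± 0.07 (adjusted p = 8.31e-05), and Hmgcs1, an early enzyme of cholesterol synthesis, fell by 0.95 ± 0.12 (adjusted p = 0.000492).

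Of the mRNAs, 9307 (51.1%) were called, 4689 higher and 4618 lower. Of those with at least a 2-fold difference, 1515 were higher and 322 lower. The groups did not overlap for 51.8% of mRNAs, where chance gives 2.86%. With slide as a block 8298 mRNAs were called, 7828 of them also called without it, and 9305 of the 9307 had the same sign within both slides. Every RNA named below as higher or lower had the same sign within both slides, and kept an adjusted p under 0.05 with slide as a block except where that value is given. This does not cover the unnamed members counted in the gene lists. For the largest differences the same sign follows from their choice, since only features whose groups do not overlap were ranked. It is equally fixed for every other RNA, of any class, whose groups do not overlap. The counts of called RNAs with the same sign within both slides therefore add little beyond the calls themselves. Each difference within a slide rests on 1 contusion array (slide 1) or 1 control array (slide 2). By the descriptions, slide 1 holds the contusion sample of day 3 and slide 2 those of days 4, 5 and 6, so slide and day cannot be told apart. Where the block lowers the number of called members of a list, that number is given.

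Among the largest increases, several began near the background and have only a bound. Gm5861 (NM_001310021) was at least 46.9-fold higher (adjusted p = 0.000327), Gml2 (NM_010416) at least 27.6-fold (adjusted p = 0.00041) and Speer1 (NM_001309520) at least 50.1-fold (adjusted p = 4.73e-05). Colec10, a collectin of innate immunity, was at least 41.1-fold higher (adjusted p = 0.000719). Tgm1, a transglutaminase of keratinocytes, rose 45.1-fold (5.49 ± 0.96, adjusted p = 0.00253). Htr2b, a serotonin receptor, rose 37.6-fold (5.23 ± 0.67, adjusted p = 0.000617). Without control replicate 4 the folds were 23.3 for Tgm1 and 22.5 for Htr2b, and without control replicate 1 the fold of Tgm1 was 76.1. Sprr2i, of a family of cornified envelope proteins, was well above background on 0 control arrays and at least 9.67-fold higher after contusion (adjusted p = 0.000105). Of the largest decreases, Myoc, the gene of myocilin, fell by 2.47 ± 0.43 (adjusted p = 0.00263), and Dao, the D-amino-acid oxidase gene, fell by 2.21 ± 0.14 (adjusted p = 8.86e-05). Also among them were Klri1, a receptor of lymphocytes (at least 3.96-fold lower, adjusted p = 8.31e-05), Cyp4f15, a lipid hydroxylase (−2.06 ± 0.24, adjusted p = 0.00042), Kirrel2 (−2.05 ± 0.27, adjusted p = 0.000663) and the aquaporin gene Aqp6 (−1.96 ± 0.20, adjusted p = 0.00026). Within slides 1 and 2, the differences were 5.61 and 3.77 for Arg1, 6.74 and 3.65 for Cd5l, 6.08 and 3.28 for Tgm1, and −2.46 and −1.97 for Myoc.

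Over the 35 gene lists, camera called 18 higher and 7 lower, 25 in all. With slide as a block 23 were called, fry called 28, and camera with an estimated correlation called 0, with 3 of 35 at an unadjusted p under 0.05 and the lowest adjusted p = 0.150 for the unfolded protein response. Each list below is therefore described by its members first. Members of a list vary together, so their counts are not counts of independent results. They are to be read beside all mRNAs, of which 4689 of 18198 were called higher and 4618 lower. The RNA came from cord tissue, so a list named for a cell type does not tell a change within those cells from a change in their share.

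**Figure D1:**
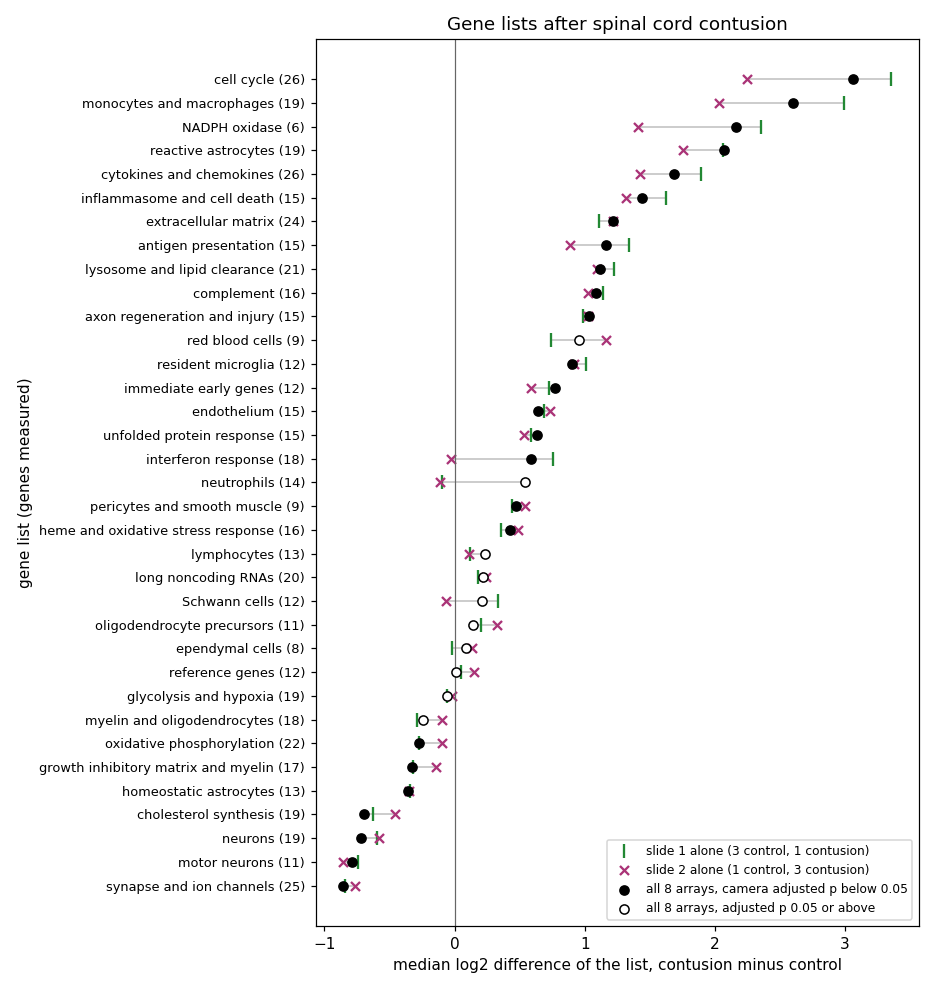
Median log2 difference between contusion and control (x axis) for the 35 gene lists (y axis), over all arrays and within each slide. A line joins the medians of a list, and the marker of the median over all arrays is filled or open by its camera call. The medians over all arrays run from −0.85 for synapse and ion channel genes to 3.06 for cell cycle genes.

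Markers of monocytes and macrophages rose in all 19 measured members (19 adjusted over the list alone; median 2.60, within slides 2.99 and 2.03). Plin2, which coats lipid droplets, rose 5.78-fold (2.53 ± 0.18, adjusted p = 0.000106). Spp1, the gene of osteopontin, rose 7.76-fold (2.96 ± 0.31, adjusted p = 0.000279), and the scavenger receptor gene Msr1 rose 35.4-fold (5.15 ± 0.57, adjusted p = 0.000336). Camera gave this list an adjusted p = 3.96e-07, and adjusted p = 0.336 with an estimated correlation. The control arrays spread widely on it, at means of 2.14, 1.34, 2.02 and 0.40 for replicates 1, 2, 3 and 4, against 4.26 to 4.45 on the contusion arrays. Of 12 markers of resident microglia 9 rose and 0 fell (10 and 0 adjusted over the list alone; median 0.90, within slides 1.01 and 0.92; 8 called with the block). Among them the fractalkine receptor gene Cx3cr1 rose by 1.17 ± 0.15 (adjusted p = 0.000565) and Olfml3 3.85-fold (1.95 ± 0.25, adjusted p = 0.000576). The list had adjusted p = 0.00225, and adjusted p = 0.459 with an estimated correlation.

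Cytokine and chemokine genes rose in 21 of 26 members, with 0 lower (21 adjusted over the list alone; median 1.69, within slides 1.89 and 1.43). Lif, a cytokine that acts on glia and neurons, rose 6.83-fold (2.77 ± 0.19, adjusted p = 0.000106). The tumour necrosis factor gene Tnf rose 11.1-fold (3.47 ± 0.32, adjusted p = 0.000189), and the chemokine gene Ccl3 rose 8.38-fold (3.07 ± 0.40, adjusted p = 0.000666). Camera gave adjusted p = 2.39e-06, and adjusted p = 0.336 with an estimated correlation. All 6 subunit genes of the NADPH oxidase, which makes superoxide in phagocytes, rose (6 adjusted over the list alone; median 2.16, within slides 2.36 and 1.41). Cyba, of the membrane subunit p22phox, rose 5.28-fold (2.40 ± 0.29, adjusted p = 0.000497). Camera gave it adjusted p = 0.00243, and adjusted p = 0.379 with an estimated correlation. Of 21 genes of the lysosome and of lipid clearance 18 rose (19 adjusted over the list alone; median 1.12, within slides 1.22 and 1.10). The protease gene Ctsl rose by 1.47 ± 0.10 (adjusted p = 9.64e-05), the lipase gene Lpl by 1.98 ± 0.15 (adjusted p = 0.000115) and the cholesterol exporter gene Abca1 by 1.83 ± 0.14 (adjusted p = 0.000117). That list had adjusted p = 2.31e-07, and adjusted p = 0.336 with an estimated correlation. Antigen presentation genes rose in 14 of 15 members (14 adjusted over the list alone; median 1.17, within slides 1.34 and 0.89; 13 called with the block; adjusted p = 2.51e-05, and adjusted p = 0.361 with an estimated correlation). B2m, the light chain of class I molecules, rose by 0.93 ± 0.09 (adjusted p = 0.000202).

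Complement genes rose in 8 of 16 members and fell in 0 (9 and 0 adjusted over the list alone; median 1.08, within slides 1.14 and 1.03; 7 called with the block). The anaphylatoxin receptor gene C5ar1 rose 9.20-fold (3.20 ± 0.21, adjusted p = 8.96e-05) and the C1q chain gene C1qa 3.33-fold (1.73 ± 0.24, adjusted p = 0.000862). Complement genes together had adjusted p = 0.00405, and adjusted p = 0.430 with an estimated correlation. Of 18 interferon response genes 8 rose and 0 fell (8 and 0 adjusted over the list alone; median 0.59, within slides 0.76 and −0.03; 5 called with the block), such as Bst2, an antiviral membrane protein (2.87-fold, 1.52 ± 0.16, adjusted p = 0.000294). Its camera call (adjusted p = 0.0247) was lost with adjusted p = 0.611 with an estimated correlation and with slide as a block (adjusted p = 0.182). Without control replicate 3 the interferon list had adjusted p = 0.0562 and without control replicate 4 adjusted p = 0.0686. Genes of the inflammasome and of cell death rose in 14 of 15 members (14 adjusted over the list alone; median 1.44, within slides 1.63 and 1.32). Ripk3, a kinase of necroptosis, rose 5.87-fold (2.55 ± 0.23, adjusted p = 0.000178) and Mlkl, its pore protein, by 2.05 ± 0.20 (adjusted p = 0.000211). That list had adjusted p = 8.65e-07, and adjusted p = 0.336 with an estimated correlation.

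Neutrophil markers gave no called shift: 5 of 14 rose and 1 fell (5 and 1 adjusted over the list alone), the median was 0.54, and the medians within slides were −0.10 and −0.12. Camera gave adjusted p = 0.212, and adjusted p = 0.818 with slide as a block, under which 3 members were called. The decoy receptor gene Il1r2 rose 3.72-fold (1.90 ± 0.18, adjusted p = 0.000205) and Ly6g, the antigen used to identify mouse neutrophils, rose by 0.76 ± 0.13 (adjusted p = 0.00220). Mmp9, a secreted protease, fell by 0.56 ± 0.14 (adjusted p = 0.0149), a call that ended with the mean of its probes (adjusted p = 0.208) and without control replicates 1 and 3 (adjusted p = 0.0615). Mean levels of this list were 0.87, −1.11, 1.07 and −0.42 on control replicates 1, 2, 3 and 4 and 0.01, 0.36, 1.47 and 1.36 on the contusion replicates, so 2 control arrays lay above 2 contusion arrays. The calprotectin gene S100a9, chosen after its values were seen, had levels of 5.82 and 6.11 on control replicates 1 and 3. It had 2.78 and 4.24 on control replicates 2 and 4, and 4.15 on contusion replicate 1. Without control replicates 1 and 3, a choice made after the values were seen, the neutrophil list was called higher (median 1.36, adjusted p = 0.0110). Lymphocyte markers rose in 4 of 13 members and fell in 0 (3 and 0 adjusted over the list alone; median 0.24, within slides 0.12 and 0.11; 2 called with the block; adjusted p = 0.212). The adhesion receptor gene Cd2 rose by 0.97 ± 0.19 (adjusted p = 0.00396) and the granzyme gene Gzma by 1.17 ± 0.30 (adjusted p = 0.0154). Of 9 red blood cell genes 5 rose and 0 fell (5 and 0 adjusted over the list alone; median 0.96, within slides 0.74 and 1.16; 2 called with the block), with the alpha globin gene Hba-a2 up 2.14-fold (1.10 ± 0.27, adjusted p = 0.0131). The red cell list was not called (adjusted p = 0.0971) but was called without control replicate 3 (adjusted p = 0.0331). Markers of skeletal muscle, a list written after a first look at the data, had mean levels of 4.30 and 2.43 on contusion replicates 1 and 2 against 0.31 and 0.10 on contusion replicates 3 and 4, and −0.69 to 1.37 on the control arrays. None of its 9 genes was called.

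**Figure D2:**
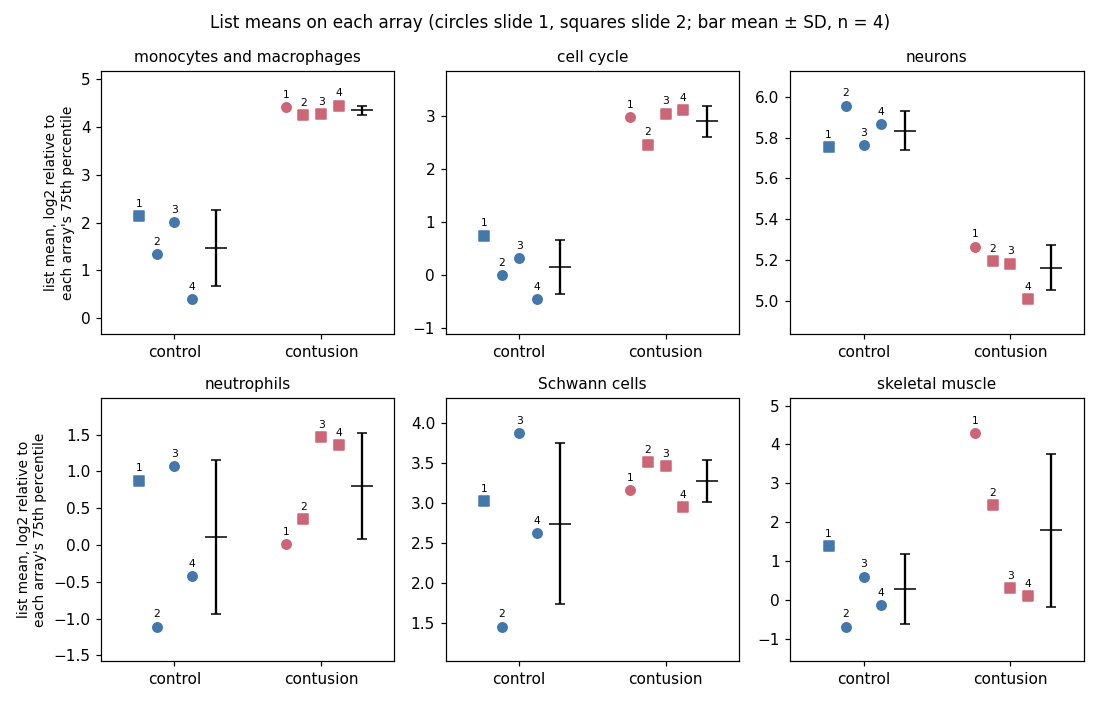
Mean level of the members of selected gene lists on each of the 8 arrays (y axis, log2 relative to the 75th percentile), by group and slide. Control replicates 1 and 3 lie at 0.87 and 1.07 for the neutrophil list, above contusion replicates 1 and 2 at 0.01 and 0.36.

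All 19 genes of reactive astrocytes rose, Timp1 and Steap4 with 3 control values each (19 adjusted over the list alone; median 2.07, within slides 2.07 and 1.75; 17 called with the block). The hyaluronan receptor gene Cd44 rose by 2.07 ± 0.13 (adjusted p = 8.32e-05), the heat shock gene Hspb1 by 2.13 ± 0.22 (adjusted p = 0.000252) and the oncostatin receptor gene Osmr by 2.02 ± 0.21 (adjusted p = 0.000284). Camera gave adjusted p = 2.31e-07, and adjusted p = 0.336 with an estimated correlation. Of 13 genes of resting astrocytes 7 fell and 2 rose (9 and 2 adjusted over the list alone; median −0.35, within slides −0.34 and −0.35; adjusted p = 0.0117, and adjusted p = 0.379 with an estimated correlation). The neurotensin receptor gene Ntsr2 fell by 1.11 ± 0.09 (adjusted p = 0.000147). Against the list, the folate enzyme gene Aldh1l1 rose by 0.88 ± 0.08 (adjusted p = 0.000209) and the water channel gene Aqp4 by 0.47 ± 0.10 (adjusted p = 0.00613).

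Myelin and oligodendrocyte genes gave no called shift, with 6 of 18 lower and 3 higher (7 and 3 adjusted over the list alone; median −0.24, within slides −0.29 and −0.10; 3 called with the block; adjusted p = 0.129). With normexp and quantile scaling camera called the myelin list lower (adjusted p = 0.0414). Opalin, a myelin membrane protein, fell by 0.48 ± 0.11 (adjusted p = 0.0106), Mbnl3, a splicing regulator, rose by 1.19 ± 0.17 (adjusted p = 0.000984), and Mbp, the gene of myelin basic protein, differed by −0.18 ± 0.09 (adjusted p = 0.136). Of 11 genes of oligodendrocyte precursors 5 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.14, within slides 0.20 and 0.32; 5 called with the block; adjusted p = 0.108). The proteoglycan gene Cspg4 rose by 0.85 ± 0.08 (adjusted p = 0.000204) and Gpr17, a receptor of early differentiating cells, rose 2.48-fold (1.31 ± 0.13, adjusted p = 0.000220). For 8 ependymal genes the median was 0.09, the mean −0.06 and camera's direction down (adjusted p = 0.927), with 1 higher and 2 lower (1 and 2 adjusted over the list alone; medians within slides −0.02 and 0.14). Ccdc153, expressed in ciliated cells, fell by 1.39 ± 0.11 (adjusted p = 0.000141) and Tmem212 by 0.88 ± 0.16 (adjusted p = 0.00335), while Rarres2, the gene of chemerin, rose by 0.81 ± 0.17 (adjusted p = 0.00539).

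Neuronal genes fell in all 19 measured members (19 adjusted over the list alone; median −0.72, within slides −0.60 and −0.58; 18 called with the block). Syt1, the calcium sensor of transmitter release, fell by 0.89 ± 0.07 (adjusted p = 0.000133), Rbfox3, which encodes NeuN, by 0.97 ± 0.09 (adjusted p = 0.000188) and the neurofilament gene Nefl by 0.72 ± 0.07 (adjusted p = 0.000233). The list had adjusted p = 2.82e-07, and adjusted p = 0.336 with an estimated correlation. Of 11 motor neuron genes 9 fell and 0 rose (9 and 0 adjusted over the list alone; median −0.79, within slides −0.74 and −0.86; 7 called with the block; adjusted p = 0.000178, and adjusted p = 0.336 with an estimated correlation). Ache, whose enzyme breaks down acetylcholine, fell by 1.10 ± 0.09 (adjusted p = 0.000150). Chat, whose enzyme makes it, fell by 0.77 ± 0.07 (adjusted p = 0.000201). Synapse and ion channel genes fell in 22 of 25 members and rose in 0 (23 and 0 adjusted over the list alone; median −0.85, within slides −0.84 and −0.76). The sodium channel gene Scn1a fell by 1.10 ± 0.09 (adjusted p = 0.000149) and the glycine receptor gene Glra1 by 0.79 ± 0.07 (adjusted p = 0.000151). Camera gave adjusted p = 2.73e-09, and adjusted p = 0.336 with an estimated correlation.

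Genes of axon injury and regeneration rose in 14 of 15 members (14 adjusted over the list alone; median 1.03, within slides 0.98 and 1.03; adjusted p = 3.28e-06, and adjusted p = 0.336 with an estimated correlation). The injury-induced transcription factor gene Atf3 rose 13.7-fold (3.78 ± 0.31, adjusted p = 0.000149), Gadd45a, a DNA damage response gene, by 1.12 ± 0.08 (adjusted p = 9.83e-05) and Sox11, of a developmental transcription factor, by 1.03 ± 0.08 (adjusted p = 0.000141). Immediate early genes rose in 8 of 12 members and fell in 1 (8 and 1 adjusted over the list alone; median 0.77, within slides 0.72 and 0.59; adjusted p = 0.00430, and adjusted p = 0.336 with an estimated correlation). Zfp36, which destabilises inflammatory mRNAs, rose by 1.25 ± 0.09 (adjusted p = 0.000121) and the AP-1 gene Junb by 1.49 ± 0.16 (adjusted p = 0.000317), whereas Arc, induced by synaptic activity, fell by 0.44 ± 0.08 (adjusted p = 0.00343).

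Cell cycle genes had the largest median of the lists: 25 of 26 rose (25 adjusted over the list alone; median 3.06, within slides 3.35 and 2.25). Mcm3 rose 6.14-fold (2.62 ± 0.11, adjusted p = 4.88e-05) and Mcm6 5.00-fold (2.32 ± 0.10, adjusted p = 4.88e-05), both subunits of the replication helicase with Mcm2. The list had adjusted p = 1.14e-11, and adjusted p = 0.336 with an estimated correlation. Extracellular matrix genes rose in 16 of 24 members and fell in 0 (20 and 0 adjusted over the list alone; median 1.22, within slides 1.11 and 1.21; 13 called with the block; adjusted p = 1.01e-05, and adjusted p = 0.402 with an estimated correlation). Thbs1, the gene of thrombospondin 1, rose 11.8-fold (3.56 ± 0.24, adjusted p = 9.75e-05) and Tnc, the gene of tenascin C, 7.82-fold (2.97 ± 0.20, adjusted p = 9.78e-05). Of 17 genes of growth-inhibitory matrix and myelin proteins 8 fell and 4 rose (9 and 4 adjusted over the list alone; median −0.32, within slides −0.32 and −0.15; 10 called with the block). Hapln1 and Hapln4, link proteins of perineuronal nets, fell by 1.70 ± 0.15 (adjusted p = 0.000172) and 1.25 ± 0.10 (adjusted p = 0.000149). The proteoglycan genes Vcan and Ncan rose by 1.10 ± 0.08 (adjusted p = 0.000114) and 0.64 ± 0.09 (adjusted p = 0.00114). Its camera call (adjusted p = 0.0422) was lost with adjusted p = 0.579 with an estimated correlation and with slide as a block (adjusted p = 0.0618). The same list had adjusted p = 0.0749 without control replicate 2, and adjusted p = 0.0511 without contusion replicate 2 or contusion replicate 3. Camera also did not call it with the mean of a gene's probes (adjusted p = 0.0789) or with scaling to spike-ins (adjusted p = 0.0645).

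Endothelial genes rose in 10 of 15 members and fell in 1 (10 and 1 adjusted over the list alone; median 0.64, within slides 0.68 and 0.74; adjusted p = 0.00225, and adjusted p = 0.336 with an estimated correlation). Emcn, an endothelial sialomucin, rose by 0.94 ± 0.09 (adjusted p = 0.000202) and the junction gene Cdh5 by 1.45 ± 0.16 (adjusted p = 0.000328). Of 9 genes of pericytes and smooth muscle 6 rose and 0 fell (8 and 0 adjusted over the list alone; median 0.47, within slides 0.44 and 0.54; adjusted p = 0.00225, and adjusted p = 0.336 with an estimated correlation). Of the contractile genes, Acta2 rose by 0.84 ± 0.07 (adjusted p = 0.000171) and Tagln 4.94-fold (2.31 ± 0.29, adjusted p = 0.000540). Schwann cell genes gave no called shift, with 2 of 12 higher and 0 lower (2 and 0 adjusted over the list alone; median 0.21, within slides 0.33 and −0.06; adjusted p = 0.438). The matrix gene Fbln2 rose 5.70-fold (2.51 ± 0.28, adjusted p = 0.000338) and the neurotrophin receptor gene Ngfr rose by 1.58 ± 0.27 (adjusted p = 0.00237). Mean levels of the Schwann list were 3.02, 1.46, 3.88 and 2.62 on control replicates 1, 2, 3 and 4, against 2.96 to 3.52 on the contusion arrays. Without control replicates 1 and 3, chosen after the values were seen, the Schwann list was called higher (median 1.35, adjusted p = 0.0252).

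Cholesterol synthesis genes fell in all 19 members (19 adjusted over the list alone; median −0.70, within slides −0.62 and −0.46; 18 called with the block; adjusted p = 3.96e-07, and adjusted p = 0.361 with an estimated correlation). The sterol sensor gene Insig1 fell by 1.15 ± 0.13 (adjusted p = 0.000328) and Lss, of the enzyme that closes the sterol rings, by 0.64 ± 0.08 (adjusted p = 0.000497). Of 22 genes of oxidative phosphorylation 10 fell and 0 rose (12 and 0 adjusted over the list alone; median −0.27, within slides −0.28 and −0.10; 5 called with the block; adjusted p = 0.000679, and adjusted p = 0.459 with an estimated correlation). Sdha of complex II fell by 0.52 ± 0.08 (adjusted p = 0.00166) and Ndufv1 of complex I by 0.52 ± 0.12 (adjusted p = 0.00824). For 19 genes of glycolysis and hypoxia the median was −0.06, the mean 0.20 and camera's direction up (adjusted p = 0.968), with 4 higher and 5 lower (4 and 5 adjusted over the list alone; medians within slides −0.06 and −0.02; 7 called with the block). The lactate dehydrogenase gene Ldha rose by 0.99 ± 0.10 (adjusted p = 0.000242), the lactate exporter gene Slc16a3 4.88-fold (2.29 ± 0.27, adjusted p = 0.000432) and the hexokinase gene Hk2 by 1.80 ± 0.23 (adjusted p = 0.000637).

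Genes of the heme and oxidative stress response rose in 8 of 16 members and fell in 2 (9 and 2 adjusted over the list alone; median 0.42, within slides 0.36 and 0.49; 6 called with the block; adjusted p = 0.0125, and adjusted p = 0.336 with an estimated correlation). The heme oxygenase gene Hmox1 rose 27.3-fold, from 2.10 ± 0.78 to 6.87 ± 0.19 (4.77 ± 0.35, adjusted p = 0.000112), and the ferritin gene Ftl1 rose by 1.98 ± 0.16 (adjusted p = 0.000135). The transferrin receptor gene Tfrc fell by 0.63 ± 0.11 (adjusted p = 0.00305). Unfolded protein response genes rose in 11 of 15 members and fell in 0 (12 and 1 adjusted over the list alone; median 0.63, within slides 0.59 and 0.54; adjusted p = 7.98e-05, and adjusted p = 0.150 with an estimated correlation). Of the endoplasmic reticulum, Sdf2l1 rose by 1.44 ± 0.09 (adjusted p = 8.32e-05) and Creld2 by 0.88 ± 0.06 (adjusted p = 0.000106). Of 12 reference genes 4 rose and 1 fell (4 and 1 adjusted over the list alone; median 0.01, within slides 0.05 and 0.15; adjusted p = 0.266). Gusb, a lysosomal enzyme, rose 4.55-fold (2.19 ± 0.21, adjusted p = 0.000222) and the actin gene Actb by 0.91 ± 0.10 (adjusted p = 0.000363). Rpl13a rose by 0.31 (adjusted p = 0.00366) but had adjusted p = 0.0604 when arrays were scaled to spike-ins, while Gapdh differed by −0.02 ± 0.07 (adjusted p = 0.843).

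The second comparison asks which lncRNAs differ between the groups. Morrbid, a lncRNA of myeloid cells that restrains a cell death gene, rose 2.59-fold (1.37 ± 0.08, adjusted p = 8.31e-05). The imprinted lncRNAs Meg3 (−0.63 ± 0.06, adjusted p = 0.000215), Peg13 (−0.99 ± 0.10, adjusted p = 0.000259) and Rian (−0.92 ± 0.11, adjusted p = 0.000553), which are abundant in neurons, fell. Of the 32 listed lncRNAs 20 were measured, 9 rose and 5 fell (9 and 6 adjusted over the list alone; median 0.22, within slides 0.18 and 0.24; 13 called with the block; adjusted p = 0.487).

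Of all lncRNAs tested, 10135 (28.7%) were called, 2602 higher and 7533 lower. At 2-fold or more, 531 were higher and 781 lower. The groups did not overlap for 27.0% of lncRNAs. With slide as a block 8510 were called, 7601 of them also called without it, and 10111 of the 10135 had the same sign within both slides. By source, 8039 of 29399 NONCODE transcripts, 1773 of 5158 Ensembl transcripts and 321 of 736 RefSeq non-coding RNAs were called, the last with 141 higher and 180 lower. Ranked by the values without bounds, an order that the bounds do not keep, the largest increases were Speer6-ps1, a pseudogene transcript that was well above background on 0 control arrays and at least 12.3-fold higher after contusion (adjusted p = 4.73e-05), NONMMUT016187 (at least 17.1-fold higher, adjusted p = 0.00022) and ENSMUST00000136927 (at least 14.8-fold higher, adjusted p = 0.000387). Both of the last were well above background on 1 control array. Of the largest decreases, NONMMUT126308 was well above background on 0 contusion arrays and at least 2.70-fold lower (adjusted p = 0.000112), NONMMUT101069 fell by 3.19 ± 0.20 (adjusted p = 8.46e-05) and ENSMUST00000214587 was at least 3.86-fold lower (adjusted p = 0.00254). All differences are relative to the 75th percentile of each array: scaled to spike-in probes instead, the median over all features was −0.18 rather than −0.05, and 13.2% rather than 25.7% of called lncRNAs were higher, 36.9% rather than 50.4% of mRNAs and 21.9% rather than 38.7% of circRNAs.

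The third comparison asks which circRNAs, closed loops made by splicing exon ends backwards, differ between the groups. The circRNA with the largest increase lay inside Lgals3, the gene of the phagocyte lectin galectin 3 (chromosome 14, 47380221 to 47384709), and rose by 4.51 ± 0.55 (adjusted p = 0.000506; within slides 5.04 and 3.53). Its fold was 22.8, and 14.7 without control replicate 4. Of the 10 largest increases 6 lay inside Top2a, a topoisomerase gene of dividing cells, among them chromosome 11, 98995244 to 98995973 (4.24 ± 0.59, adjusted p = 0.000851) and 99009230 to 99011063 (4.17 ± 0.55, adjusted p = 0.000677). Others lay inside Pbk, a mitotic kinase gene (chromosome 14, 65809215 to 65813976; at least 15.3-fold higher, adjusted p = 0.00241), and Uhrf1, a gene that maintains DNA methylation (chromosome 17, 56305086 to 56322125; at least 11.9-fold higher, adjusted p = 0.000112). Positions are those of the circRNA names, whose genome build the sources used here do not state.

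Of the circRNAs tested, 14944 (42.0%) were called, 5778 higher and 9166 lower. At 2-fold or more, 951 were higher and 212 lower. The groups did not overlap for 43.7% of circRNAs. With slide as a block 12798 were called, 12048 of them also called without it, and 14932 of the 14944 had the same sign within both slides. Decreases were smaller than increases. The circRNA inside Rasal1, a Ras regulator gene (chromosome 5, 120654806 to 120655129), fell by 1.74 ± 0.32 (adjusted p = 0.00313), and that inside Etl4 (chromosome 2, 20529959 to 20713448) by 1.45 ± 0.17 (adjusted p = 0.000463). The circRNA inside Zbbx (chromosome 3, 75136414 to 75155501), well above background on 0 contusion arrays, was at least 2.21-fold lower (adjusted p = 0.0300), a bound that falls to 1.41 without control replicate 4. With slide as a block it had adjusted p = 0.0962, without contusion replicate 1 it had adjusted p = 0.0643 and without contusion replicate 3 adjusted p = 0.0782.

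Set by position against the mRNA of the 1 gene around it, an analysis chosen after the data were seen, 34149 circRNAs lay in 6627 genes with a tested mRNA. The circRNA in Lgals3 rose by 4.51 and its gene by 4.38, and the circRNA in Top2a at 98995244 rose by 4.24 and its gene by 4.18. Where circRNA and gene were both called, 11336 of 11668 pairs (97.2%) had the same direction, 4033 higher and 7303 lower, and over all pairs the share was 79.3%. Across the 6627 genes, with the circRNAs of each gene averaged, the differences of circRNAs and mRNAs correlated with Pearson's r of 0.836 and Spearman's rho of 0.801. Neither the genes nor the pairs are independent replicates, and single circRNAs were not correlated with their gene. By list, many circRNAs came from few genes, so the counts are not of independent results. Of circRNAs inside 13 cell cycle genes 52 of 54 rose (median 2.47). So did 50 of 50 inside 7 genes of reactive astrocytes (median 1.70) and 14 of 14 inside 4 macrophage genes (median 2.12). Inside 16 extracellular matrix genes 106 of 167 rose (median 1.12, 1 lower). Inside 20 synapse and ion channel genes 131 of 161 fell and 1 rose (median −0.46). Inside 8 neuronal genes 47 of 56 fell (median −0.59) and inside 9 cholesterol synthesis genes 36 of 42 fell (median −0.47). In 332 pairs circRNA and gene were called in opposite directions, 0 of them with at least 2-fold on both sides. Also, 2668 called circRNAs lay in genes whose mRNA was not called. The circRNA inside Dpyd, of pyrimidine breakdown (chromosome 3, 118915205 to 118944335), was at least 2.43-fold lower (adjusted p = 0.00662) while the gene's mRNA, at 0.15, was not called. The circRNA inside Fggy, a sugar kinase gene (chromosome 4, 95828015 to 95849676) was at least 1.75-fold lower (adjusted p = 0.00508) while the gene differed by −0.03 (adjusted p = 0.729).

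**Figure D3:**
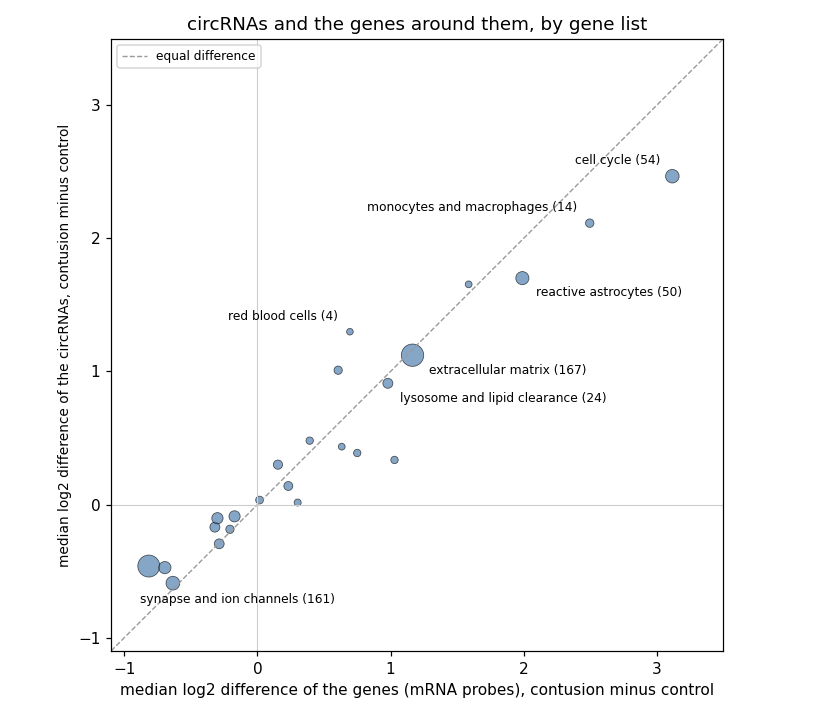
Median log2 difference of the circRNAs inside genes of each list (y axis) against the median of those genes' mRNAs (x axis), contusion minus control, with the symbol area growing with the number of circRNAs and the dashed line marking equal differences. Cell cycle genes stand at 3.12 for the genes and 2.47 for their 54 circRNAs, and synapse and ion channel genes at −0.82 and −0.46.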

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

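No test in this part was chosen after its result was seen. For each of 488 groups of 4 values (35 list means, 6 array measures and 203 named features, each in controls and in contusion samples), it was asked whether 1 array stood far from the other 3. An array counts as apart when its gap to the nearest of the others, divided by the whole range, exceeds Dixon's 95% critical value. That was so in 26 groups (5.33%), and chance sets apart about 1 group in 20, so the number of such groups gives no ground for removing an array. Levels are log2 values relative to each array's 75th percentile.

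Control replicate 4 stood apart for 1 list and 6 features. Its mean over the lysosome and lipid clearance list was 4.14, against 4.49 to 4.55 on the other control arrays. Its level of the complement gene C1qa was 5.79 (others 6.79 to 6.92), of the lipid droplet gene Plin2 2.88 (highest other 3.56) and of the AP-1 gene Junb 3.11 (others 3.77 to 3.85). The circRNA inside Lgals3 was at −0.73 (others 1.63 to 2.06) and Creld2, of the endoplasmic reticulum, at 4.11 (others 4.23 to 4.25). The circRNA inside Zbbx was high, at −2.14 (others −4.86 to −4.67). Values of 1 array are not independent of each other, so these do not count as separate signs that it differs.

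Among the other controls, replicate 1 stood apart for Klri1 at −3.43, for Opalin of the myelin sheath at 5.46 (others 5.83 to 5.84), for ENSMUST00000129601 at −7.02 and for the circRNA inside Top2a at chromosome 11, 98994207 to 98995378, at −5.43 (others −7.95 to −7.78). Control replicate 3 stood apart for Ngfr, a receptor of Schwann cells, at 1.10 (others 0.18 to 0.29).

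Contusion replicate 2 had a red blood cell list mean of 3.41 (others 2.50 to 2.64), an NADPH oxidase list mean of 2.24 (others 2.46 to 2.49) and an immediate early gene list mean of 2.81 (others 2.70 to 2.71). It also stood apart for Cd44 at 4.39 (others 4.24 for each), Ccdc153 at 0.46 (others 0.14 to 0.18) and Rarres2 at 4.07 (others 3.77 to 3.81). Contusion replicate 1 stood apart for Olfml3 at 6.58 (others 6.68 to 6.71), the T cell kinase gene Lck at −2.42 (others −2.16 to −2.11), Sntn of cilia at 0.52 (others 1.39 to 1.56) and ENSMUST00000196720 at −7.71. Contusion replicate 3 stood apart for NONMMUT114062 at −3.17 and NONMMUT126308 at −6.41, and contusion replicate 4 for Tgif1 at 3.05 (others 2.86 to 2.89) and for the reference gene mean at 5.43 (others 5.46 to 5.47).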

How the results depend on the processing

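Leaving out control replicates 1 and 3 together, contusion replicate 1 alone against the controls, scaling to spike-ins and the folds without each array were chosen only after the results were seen. Over the alternatives run, no named feature changed its direction while called, and no list did in the 24 alternatives that tested lists. Within slide 2 alone, 24 of the 25 called lists kept the sign of their median. The interferon response list did not (−0.03). Of 840 list comparisons (35 lists, 24 alternatives) 796 stayed on the same side of the threshold, 36 lost a call and 8 gained a call. Of 5235 comparisons of 203 named features, 183 lost a call, 95 of them with contusion replicate 1 alone, and 20 gained a call. The circRNA and positional gene share of same direction, 97.2% as reported, ran from 96.1% to 99.3% over 24 alternatives (lowest with array weights, highest with contusion replicate 1 alone). Of these, 19 lay outside its binomial interval. That interval takes the pairs as independent, which they are not, so it is too narrow to judge whether the share moved.

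The number of called lists depended most on the correlation assumed between genes: camera called 25 lists at a preset correlation, fry 28 and camera with an estimated correlation 0, with 3 at an unadjusted p under 0.05. The cause was not tested.

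Demanding at least a 2-fold difference left 1837 mRNAs, 1312 lncRNAs and 1163 circRNAs. With a 2-fold threshold, Welch's test gave 1799, 1254 and 1142 unadjusted, and 1631, 992 and 1028 adjusted. Testing all probes singly gave 22052 mRNA probes, since many genes have several. Contusion replicate 1 alone against the controls, a fit in which the lone array is assumed to vary like the controls, gave 2497 mRNAs, 2940 lncRNAs and 3330 circRNAs, as fewer arrays were compared, and 23 lists. All other alternatives kept the 3 counts within 1.5 times of the values reported. The lowest of these for lncRNAs was 6769, with normexp and percentile scaling.

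Leaving out each array in turn gave 7928 to 9610 mRNAs, 8032 to 10959 lncRNAs, 12232 to 14825 circRNAs and 24 to 25 lists. Without 1 array, the fold of 10 of 193 called named features moved by over 1.5 times, 8 of them most without control replicate 4, and all 193 kept their sign. A fixed block for slide gave 8298, 8510 and 12798 called features and 23 lists. Slide as a random block gave 9213, 9854 and 14659 features, with a correlation of 0.0742 within slides, and was not run for lists. With the replicate number as a block, 7469, 8426 and 11657 features and 25 lists were called, but the numbers do not pair the animals. Leaving out control replicates 1 and 3 gave 30 lists, as neutrophils (adjusted p = 0.0110), lymphocytes (adjusted p = 0.0443), red blood cells (adjusted p = 0.0242), myelin (adjusted p = 0.0221) and Schwann cells (adjusted p = 0.0252) gained a call. The cause was not tested by that alternative.

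Splitting the 8 arrays into 4 and 4 in all 35 ways, 1 split, the real split, gave as many called mRNAs, lncRNAs or circRNAs. This argues against a chance split for these 3 counts, at the smallest share that 35 splits can give. It does not exclude chance, since the other splits mix contusion and control arrays, which widens the spread within their groups. The real values were 9307, 10135 and 14944, and the highest among the other splits 52, 367 and 78, each for the split that follows the slides most closely. For lists, 8 of the 35 splits gave at least the real 25. The highest number among the other splits was 28, reached by 3 of them, 1 of which follows the slides, and the median of the others was 17. All other splits with at least 25 lists kept 3 arrays of each group together, and so kept much of the real contrast. Splits that mix the groups evenly gave 0 to 21 lists. For the number of lists by camera with a preset correlation, the splits therefore neither exclude chance nor show what chance alone gives. The lists are described by counts of called members instead, which do not remove the problem, since members of a list vary together (estimated correlation up to 0.913). Blocking on slide, 23 lists were called.

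Signal over background limits the dim features. Of the called lncRNAs 9526 lay below the median mRNA level and 609 at or above it, and for features well above background in 1 group only a bound on the fold is given.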

Other observations

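The positional analysis of circRNAs and the tests on injured RNA in the controls, on a common shift and on spike-in scaling were chosen only after the results were seen. The features of the next paragraph were also chosen after their values were seen.

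In some genes circRNA and mRNA moved apart. Cit encodes citron kinase of dividing cells and a shorter neuronal form. Its mRNA NM_007708 fell by 0.77 ± 0.07, while a circRNA inside it (chromosome 5, 115859198 to 115873994) was at least 3.52-fold higher and another with the same start at least 3.39-fold higher. In Espl1, the separase gene of mitosis, the mRNA rose by 2.53 ± 0.23 and a circRNA (chromosome 15, 102312936 to 102314096) fell by 0.83 ± 0.12. In Pde4d, a cyclic AMP phosphodiesterase gene, the mRNA fell by 0.80 ± 0.07 and a circRNA (chromosome 13, 108860075 to 109032697) rose by 1.21 ± 0.16, and in Grin2b, of an NMDA receptor subunit, the mRNA fell by 0.78 ± 0.08 and a circRNA was at least 1.70-fold higher. Positions alone do not show which transcript a circRNA comes from.

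Neutrophil and Schwann cell markers spread widely within the groups, and control replicate 3 had a Schwann list mean of 3.88, above all 4 contusion arrays (highest 3.52). RNA of injured cord in the controls stays open: over 174 mRNAs the 90th percentile of the share needed was 5.37 and 15.8 times the 10th for control replicates 1 and 3, but replicate 2 gave no ratio, and how far gene noise alone spreads the shares was not tested. By list the median share for control replicate 1 was 11.3% to 16.0% for cell cycle, matrix, macrophage and reactive astrocyte genes and 5.09% for axon injury genes, and for control replicate 3 it was 42.5% for matrix and 6.33% for cell cycle genes. For control replicate 2 it was −8.77% for matrix genes, 3.04% for cell cycle genes and 9.965% for reactive astrocyte genes. A negative share means a level below that of control replicate 4, against which the shares were computed. Array deviations from the group mean of the neutrophil list followed those of bone marrow precursors, such as Prtn3 (Pearson's r = 0.979, Spearman's rho = 0.881, 8 arrays, exact permutation adjusted p = 0.0104 and 0.0208 over 6 relations; r = 0.972 without control replicates 2 and 3). Those of the Schwann list followed a second list of peripheral nerve (r = 0.9995, rho = 0.976, exact permutation adjusted p = 0.0104 for both; r = 0.995 without the same 2 arrays). Marrow and nerve root tissue in varying amounts may explain the spread and stay open, and no biological explanation was tested. Lists that vary together do not show which tissue or cells the RNA came from. The marrow genes did not all vary alike: SDs in controls and contusion samples were 1.36 and 0.76 for Cebpe but 0.12 and 0.10 for Vpreb3.

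The Schwann list shares 3 of its 12 genes with other lists, and 12 of 14 neutrophil, 11 of 12 Schwann, 9 of 12 marrow and 7 of 7 second nerve genes were well above background on all arrays. The other relations did not pass: neutrophils with bone (r = 0.804, rho = 0.452, exact permutation adjusted p = 0.0694), with skeletal muscle (r = −0.198, rho = −0.0238, adjusted p = 0.717 by exact permutation) and with Schwann cells (r = 0.721, rho = 0.786, adjusted p = 0.125 by exact permutation), and Schwann cells with sensory ganglion neurons (r = −0.00688, rho = 0.143, adjusted p = 0.997 by exact permutation). Some of these pooled values hide unlike groups of 4 arrays. Neutrophils with skeletal muscle had r = 0.905 in controls and −0.975 in contusion samples. Neutrophils with Schwann cells had r = 0.931 and −0.136, and the groups were not tested singly. Median differences between the groups were 0.15 for marrow precursors, 0.03 for bone, 1.36 for skeletal muscle, 0.37 for the second nerve list and −0.13 for ganglion neurons. Levels on control replicates 1, 2, 3 and 4 were 1.10, 0.50, 1.29 and 0.65 for the marrow gene Prtn3 and 6.65, 5.57, 7.48 and 6.28 for Pmp22 of peripheral myelin. The muscle gene Acta1 reached 5.91 on contusion replicate 1. Cebpe, Vpreb3, Prtn3, Pmp22 and Acta1 were chosen after their values were seen.

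More lncRNAs were lower than higher, 7533 against 2602. Dim probes near the background are argued against as the cause, since 71.3% of the called lncRNAs at or above the median mRNA level were lower, 434 of 609, against 74.5% of the dimmer ones, although negative controls rose from a net signal of 7.72 to 8.71 (exact permutation p = 0.0286, the smallest that 4 against 4 arrays allow, adjusted p = 0.0381). A common shift alone cannot tell scaling to the 75th percentile apart from a change of the lncRNAs. With all contusion values raised by 0.07, which puts the lncRNA median at 0, 62.8% of the called lncRNAs were lower. With 2 times that shift 48.6% were lower, but that shift puts the lncRNA median above 0, at 0.07, and so itself favours higher calls. The shifts leave it open because a scaling error moves every RNA alike by an unknown amount. As the cause, such an error would need contusion values to be raised. The spike-ins stood at 2.34 in controls and 2.47 after contusion relative to the 75th percentile (the same exact permutation p = 0.0286, adjusted p = 0.0381). Scaling to them lowered contusion values instead. The medians of mRNAs and lncRNAs fell together, to −0.13 and −0.20, and 13.2% of called lncRNAs were higher. These values argue against a scaling error as the cause, as far as the spike-ins track the amount of RNA, which was not tested. The difference between the groups in injury itself also stays open and was not tested apart from the amount of RNA.

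CircRNAs changed with the gene around them. Random pairing of circRNAs and genes is argued against: 0 of 10000 random pairings gave as large a share of the same direction as the 97.2% observed, and the highest gave 58.2% (the smallest share they can give is 1e-04). Signal of the linear transcript on the circRNA probes cannot be told apart from a change of the circRNAs, since the median ratio of circRNA to gene difference was 0.773 over 1713 pairs (interquartile range 0.467 to 0.987) and 0.988 over 66 bright pairs. What keeps it open is that the labels describe labelled total RNA and name no step that removes linear RNA.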
